A study of Caenorhabditis elegans with 12 samples.

How the data were processed

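Small RNA under 200 nt was isolated from synchronized larval stage 4 worms grown at 20 °C, labelled with the NCode system and hybridised to 2-colour NCode microRNA arrays, per the labels' protocols. N2 RNA carried the dye named Alexa Fluor 3 and the strain's RNA the dye named Alexa Fluor 5 on every array, per the labels, so no dye swap separates the dye bias of a probe from a change in a strain. The deposited scanner files hold, for 4608 spots per array, a signal intensity per channel and a flag letter per channel, per the file headers. No background column was given, and a C. elegans spot held an intensity above 0 only with the flag C or S, so the intensities were taken as already corrected for background, and above background was taken to mean a signal above 0. The method behind that step and the meaning of the flags are not given in the sources used here. The authors' deposited value table holds log2 ratios, per the file headers and the comparison with the scanner values. Its scale was log2, its direction second over first channel and its centring the ratio of summed signals in the 10 columns that could be matched, with column medians from -0.06 to 0.40. For the cat-1 replicate 4 column these remain unknown. The column medians were 0.07, 0.27, -0.06 and 0.40 for alpha-synuclein replicates 1 to 4, -0.03, 0.08, 0.03 and 0.13 for cat-1 and 0.20, 0.05, 0.19 and -0.03 for pdr-1. Which of the scanner's letters stands for which dye is not stated, and signal B was taken as the strain from the order of channels in the labels. The table names 0 further columns of per-sample values.

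Each array held 114 C. elegans probes of 3 spots, 342 in all, beside 939 probes named by a number, controls and blanks. Spots with an S flag were left out. The log2 ratio of each spot was normalized within the array by loess on C. elegans spots (span 0.3, 4 iterations, control and other spots with negligible weight), and spots of a probe were averaged. A probe was tested if it held a signal in at least 1 channel on at least 4 of the 11 distinct arrays, which kept 50. A ratio needs a signal in both channels, so the number of arrays behind a value differs between microRNAs. On alpha-synuclein, cat-1 and pdr-1 arrays, 5, 1 and 2 probes held a strain signal and no N2 signal on any array, and no fold is given for these. Of 114 microRNA genes named on the probes, 108 matched a symbol of the WBcel235 gene table, which was used for names and neighbours only.

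Ratios were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 1 mean per strain and 1 spread over all strains, two-sided, with Benjamini-Hochberg adjustment per comparison at 0.05. The estimated prior degrees of freedom were infinite, so that all microRNAs shared 1 SD of 0.64. The ratio against 0 was the test of a strain against N2, and N2 was present only as the partner on each array. Of 12 lists fixed before the data were examined, 6 had at least 3 tested members. They were tested with camera on the moderated statistics (preset correlation 0.01, and an estimated correlation beside it). The self-contained fry test takes no missing ratios and was not run, and an exact sign-flip test of a list's mean per array was added in its place. The other lists are given as counts. The planned fit named 12 arrays and 9 residual degrees of freedom, and the repeated cat-1 file reduced the arrays to 11.

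The microRNAs named in the text followed a rule fixed before the data were examined. For each strain against N2 these were all past the threshold up to 25 by size, followed by the next by p-value up to 10 in all. The measured members of the let-7, miR-63 and miR-35 families, lin-4, lsy-6, miR-124 and miR-1 were added in each strain. For strain contrasts these were the calls up to 10, or otherwise the first 3. Names that come from alternative settings or from tests of explanations were chosen after their values were seen.

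The steps were tested on simulated data with the real pattern of missing ratios and each strain's own spread. Over 50 simulations of the 50 tested microRNAs, log2 changes of 1 were recovered in 46.5% of cases in the alpha-synuclein comparison with N2, 28.3% in cat-1 and 30.6% in pdr-1. Changes of 2 were recovered in 94.0%, 86.2% and 89.6%. With no change simulated, the alpha-synuclein comparison with N2 gave 0.42 calls on average and at most 3, while cat-1 and pdr-1 gave 0. Alternatives concerned normalization, filters, flags, averaging, the model, replicate blocks, thresholds, each array left out and the deposited table. Background alternatives could not be run, as the files give no background, and slide or scan blocks were not run, as the files give none.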

Results

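MicroRNA levels were measured in 3 Caenorhabditis elegans strains used as models of Parkinson's disease, each set against the wild-type strain N2 on the same 2-colour array. The first strain carries a human alpha-synuclein A53T transgene, the form of the protein found in a familial form of the disease. The second is a cat-1 mutant (CB1111), which lacks the vesicular transporter that loads dopamine and other monoamines. The third is a pdr-1 mutant (VC1024), which lacks the worm orthologue of the ubiquitin ligase parkin. The labels give 4 independent worm populations per strain and N2 small RNA from 4 preparations, all taken at larval stage 4. The comparison of each strain with N2 asks which microRNAs differ in that model, and the comparisons between strains ask whether the models differ from each other.

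The scanner files of cat-1 replicates 3 and 4 held identical values and were counted as 1 array, which left 11 distinct arrays: 4 for alpha-synuclein, 3 for cat-1 and 4 for pdr-1. Of the 114 C. elegans probes, 40 gave no signal on any array and 7 gave a signal on every array. The 50 probes with a signal on at least 4 arrays were tested. The number of probes with a ratio ranged from 13 to 54 per array, and it was lowest on alpha-synuclein replicate 4 (13 probes) and pdr-1 replicate 1 (14 probes). The number of arrays limits the precision of every value below. Replicates also agreed poorly in 2 strains. The median correlation of log2 ratios between pairs of arrays was 0.111 within alpha-synuclein, 0.074 within pdr-1 and 0.480 within cat-1. Between arrays of different strains it was 0.138, so alpha-synuclein and pdr-1 replicates were no more alike than arrays of different strains. The 8 probes of the miR-35 family, which is abundant in embryos, gave too little signal to be tested, and lsy-6, which sets the left-right identity of a pair of taste neurons, gave no signal.

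The strain and N2 channels were most alike on cat-1 replicates 1 and 2. The correlation of log2 signals across spots was 0.713 to 0.977 on the cat-1 arrays, against 0.387 to 0.573 for alpha-synuclein and 0.407 to 0.721 for pdr-1. The residual SD of the log2 ratios between arrays was 0.81 for alpha-synuclein, 0.47 for pdr-1 and 0.38 for cat-1. The test used 1 spread of 0.64 for all strains, which lies below that of alpha-synuclein and above those of the mutants. The p-values against N2 are thus too small for alpha-synuclein and too large for the mutants. The cat-1 arrays also stood apart in a technical measure: 15 to 18 of their blank spots held a signal, against 3 on pdr-1 replicate 2 and 0 on the other arrays. A difference between array batches and the cat-1 mutation therefore cannot be told apart from these files.

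**Figure D1:**
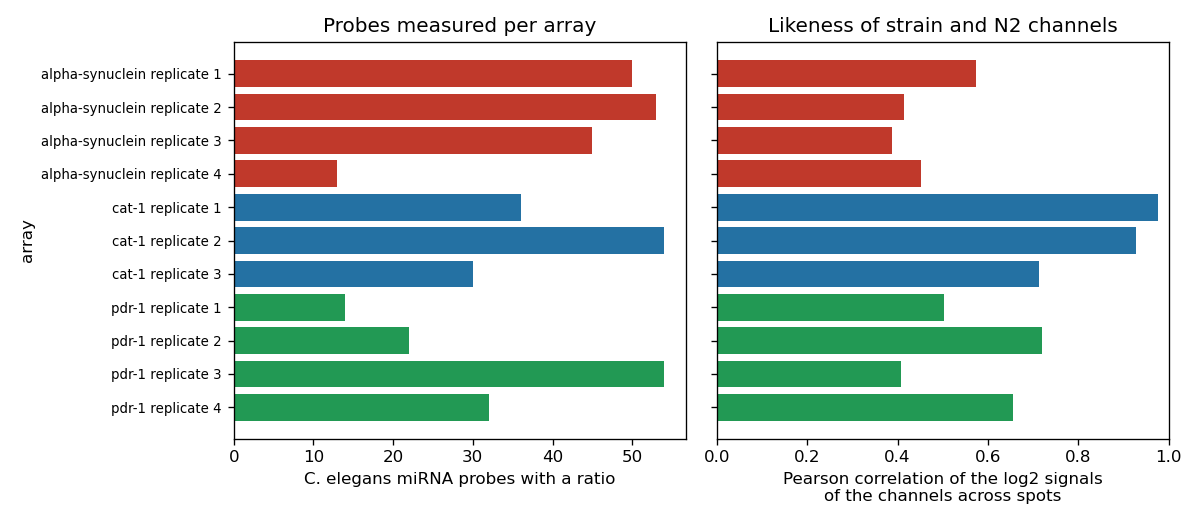
Horizontal bars give, for each of the 11 distinct arrays, the number of C. elegans probes with a ratio (left, 13 to 54) and the Pearson correlation of the log2 signals of its channels across spots (right, 0.387 to 0.977). Colours mark the strains, and cat-1 replicates 1 and 2 hold the highest correlations (0.977 and 0.927).

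In the alpha-synuclein strain, 5 of 50 microRNAs differed from N2 by limma with Benjamini-Hochberg adjustment, 3 lower and 2 higher. All signs take the ratio as strain over N2, which is the likely direction: the labels name N2 as the first channel and the strain as the second on every array, and the deposited table is the second signal over the first. let-7, a regulator of the larval-to-adult transition, was 3.49-fold lower (log2 change -1.80 ± 0.37 SE, 3 of 3 measured arrays lower, adjusted p = 0.00011). miR-70 was 2.61-fold lower (-1.38 ± 0.37, 3 of 3 arrays, adjusted p = 0.00611), and miR-48, a relative of let-7, was 1.92-fold lower (-0.94 ± 0.32, 4 of 4 arrays, adjusted p = 0.0457). miR-236 was 2.76-fold higher on the 2 arrays that measured it (1.46 ± 0.45, adjusted p = 0.0244), at 2.01 on replicate 1 and 0.92 on replicate 2. miR-34, linked to stress responses and ageing, had a mean of 1.06 ± 0.37 (adjusted p = 0.0457), but its 3 arrays spread by an SD of 1.89 and 1 of them lay below 0.

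The next microRNAs by p-value in the alpha-synuclein strain did not pass. miR-235 had a log2 change of 1.74 on a single array (adjusted p = 0.0604) and miR-84 one of -0.99 on 3 arrays (adjusted p = 0.0604). miR-83 (0.85 on 3 arrays), miR-72 (0.74 on 3) and miR-53 (-0.64 on 4) had adjusted p-values of 0.142, 0.234 and 0.234. The muscle microRNA miR-1 stood at -0.16 (n = 4), the neuronal miR-124 at 0.47 (n = 2) and lin-4, which times early larval fates, at -0.51 with an SD of 1.61 (n = 3). None of these was past the threshold. Leaving out 1 array of the strain moved most named values against N2 that did not pass by over 1.5 times: 12 of 13 measured on at least 2 arrays in the alpha-synuclein strain, 15 of 17 in cat-1 and 13 of 15 in pdr-1.

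The calls in the alpha-synuclein strain depended on the normalization within arrays and rested on few arrays. Without that normalization 18 microRNAs passed, 18 higher and 0 lower, with 1 of the 5, miR-34, among them, and let-7, miR-70 and miR-48 turned to 0.19, 0.36 and 0.63. Centring on dye controls gave 0 calls. Without alpha-synuclein replicate 1 only let-7 passed (-1.76, adjusted p = 0.0388), and without replicate 2 only miR-70 passed (-2.01), with let-7 at -1.21 and an adjusted p of 0.0827. Without replicate 3, let-7, miR-34 and miR-48 passed. Without replicate 4, miR-48 stood at -0.57 (adjusted p = 0.395). Without replicate 4, any cat-1 array or any of pdr-1 replicates 2, 3 and 4, let-7, miR-70 and miR-236 passed, and without pdr-1 replicate 1 all 5 did. Leaving out an array of another strain changed these calls only through the spread shared by the strains. The log2 changes themselves stayed as they were, at -1.80 for let-7 and -1.38 for miR-70. Fitting the strain alone left let-7 as the 1 call, and a plain test per microRNA without limma's shared spread left 0.

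Taken as a group, the let-7 family was lower in the alpha-synuclein strain relative to the other tested microRNAs, while its mean against N2 turned to 0.73 without normalization within arrays and to 0.51 with dye-control centring. The 4 measured members were let-7, miR-48, miR-84 and miR-241, and their mean log2 change was -1.09, with 4 of 4 below 0 (camera list test, adjusted p = 0.00023 over 6 lists). With an estimated correlation between members the adjusted p was 0.00279. Adjusted over the list alone, 3 members passed (let-7, miR-48 and miR-84), against 2 over all tested microRNAs. The mean of miR-84 came mostly from replicate 1 (-2.75), with replicate 2 at -0.27 and replicate 3 at 0.06. The mean of the measured members lay below 0 on 4 of 4 arrays, between -2.05 and -0.27, with miR-48 as the lone measured member on the lowest, replicate 4. An exact two-sided sign-flip test over arrays gave p = 0.125, the smallest that 4 arrays allow. miR-48 and miR-241 are neighbours in the gene table.

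**Figure D2:**
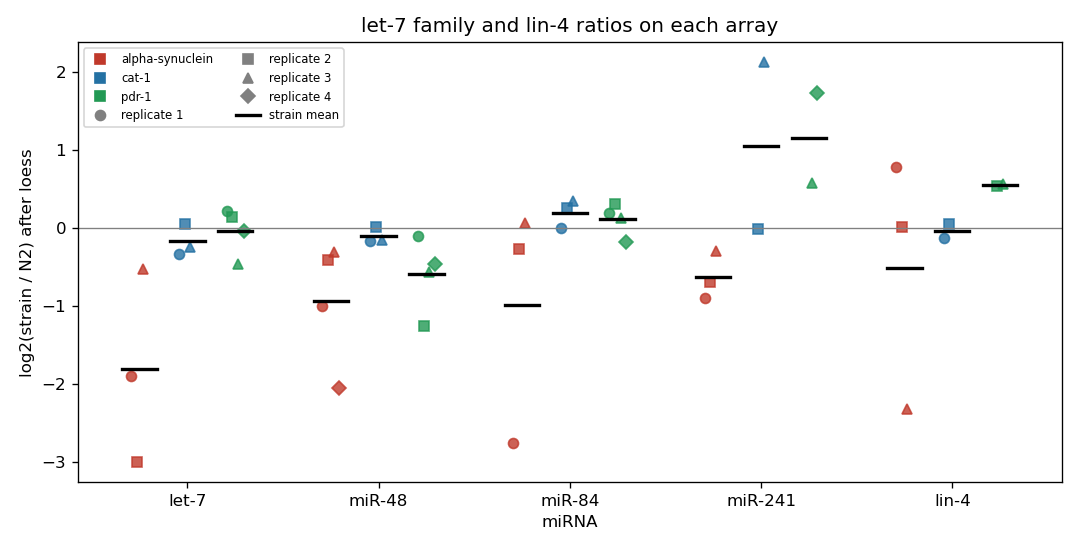
Points give the log2 ratio of strain over N2 on each array for the 4 measured let-7 family members and lin-4, with colour for the strain and shape for the replicate, and black bars give strain means. The alpha-synuclein mean of let-7 is -1.80, against -0.17 in cat-1 and -0.04 in pdr-1; without any normalization within arrays the alpha-synuclein mean of let-7 turns to 0.19.

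No other list passed in the alpha-synuclein strain. The 5 members of the miR-63 family had a mean of -0.14 (adjusted p = 0.552), with miR-64 at -0.57, miR-66 at -0.34, miR-65 at -0.27, miR-229 at 0.29 and miR-63 at 0.17. The miR-51 family had a mean of 0.01 with a median of -0.04 over 6 members (adjusted p = 0.835), and the miR-58 family one of -0.22 over 4 (adjusted p = 0.508). The 3 members of the miR-72 family all lay above 0, with a mean of 0.57 (adjusted p = 0.317). The 4 measured stress and lifespan microRNAs had a mean of 0.47 (adjusted p = 0.317), and 1 of them, miR-34, was past the threshold. The lin-4, miR-2 and miR-44 families, the neuronal list and the muscle list had 1 tested member each and 0 past the threshold.

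In the cat-1 mutant, 0 of 48 microRNAs differed from N2 by limma, and 4 had an unadjusted p under 0.05. These were miR-241 (log2 change 1.05, with 1 of 2 arrays above 0, and -0.02 without replicate 3), miR-58 (0.85 ± 0.37 SE, 3 of 3 arrays above 0), miR-71 (0.93, 2 of 2 arrays, and 0.31 without replicate 3) and miR-72 (0.92, 2 of 2 arrays, and 0.47 without replicate 3), each with an adjusted p of 0.543. miR-58 is among the most abundant worm microRNAs, and miR-71 is linked to lifespan. Fitted on the cat-1 arrays alone, with their smaller spread, the same 4 microRNAs passed. The plain test per microRNA gave 0.

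Further down the cat-1 list, miR-64 stood at -0.53 and miR-65 at -0.53, both below 0 on 3 of 3 arrays, and miR-66 at 0.47 on 2 arrays. miR-51 (-0.55), miR-53 (-0.41) and miR-252 (-0.38) followed, with adjusted p = 0.976 for all of these. The remaining members of the let-7 family, let-7 (-0.17), miR-84 (0.20) and miR-48 (-0.11), and of the miR-63 family, miR-63 (-0.15) and miR-229 (-0.05), did not pass, nor did miR-1 (0.13), miR-124 (0.33 on 1 array) and lin-4 (-0.04). The family means were 0.24 for let-7 (adjusted p = 0.450) and -0.16 for miR-63 (adjusted p = 0.193). The miR-72 family had a mean of 0.57, the miR-51 family -0.18, the miR-58 family 0.20 and the stress and lifespan list 0.16, with adjusted p-values of 0.193, 0.193, 0.450 and 0.488.

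In the pdr-1 mutant, 0 of 48 microRNAs differed from N2 by limma, and 2 had an unadjusted p under 0.05. miR-241 stood at 1.15 ± 0.45 SE on 2 of 2 arrays (adjusted p = 0.584), and it was the 1 member of the let-7 family past the threshold when adjusted over the list alone (adjusted p = 0.0486), on the higher side. With pdr-1 replicate 4 turned, miR-241 stood at -0.57 and did not pass over the list alone (adjusted p = 0.536). miR-77 stood at 0.90 on 2 of 2 arrays (adjusted p = 0.902). Fitted alone, and with the plain test per microRNA, the pdr-1 arrays gave 0 calls. miR-48 lay below 0 on 4 of 4 arrays, with a mean of -0.60 ± 0.32 (adjusted p = 0.902), and at -0.36 with replicate 4 turned.

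The other values in the pdr-1 mutant had adjusted p-values of 0.902 or more. miR-83 (0.67), miR-230 (0.65) and lin-4 (0.55) lay above 0 on both arrays that measured them, and miR-70 (-0.52) below 0 on both. miR-47 (1.00) and miR-90 (0.86) were measured on 1 array each, and miR-51 stood at 0.43 on 3 arrays. In the miR-63 family, miR-66 was at -0.51, miR-64 at -0.32, miR-65 at -0.28, miR-63 at 0.29 and miR-229 at 0.19. let-7 (-0.04), miR-84 (0.11), miR-1 (-0.20) and miR-124 (-0.44 on 1 array) completed the list. The let-7 family mean was 0.16 (adjusted p = 0.874) and the miR-63 family mean -0.13 (adjusted p = 0.610). The miR-51, miR-58, miR-72 and stress lists had means of 0.11, -0.19, 0.11 and 0.21, with adjusted p-values of 0.874, 0.610, 0.874 and 0.874.

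The direction of the pdr-1 ratios is not settled. Replicates 1 and 4 of this strain had the same dyes, yet their log2 ratios correlated at -0.564 across the 14 microRNAs measured on both, which are not independent replicates (permutation p = 0.0615). This pair was singled out as the lowest of all pairs of arrays, and its p-value was not adjusted for that. With median centring in place of loess its correlation was -0.219. Replicate 4 as taken correlated at 0.422 with replicate 3 (31 microRNAs) and at 0.047 with replicate 2 (16). Replicate 1 as taken correlated at 0.101 with replicate 2 (12) and at 0.039 with replicate 3 (14). A turned array therefore cannot be told apart from noise. With the sign of either array turned, the pdr-1 mutant again had 0 calls against N2 and the contrast of alpha-synuclein with pdr-1 kept its 1 call. The let-7 family difference of alpha-synuclein and pdr-1, -1.25 as taken, was -1.21 with replicate 1 turned and -0.90 with replicate 4 turned (adjusted p = 0.000111 and 0.00221). Of the 19 named pdr-1 values, 3 changed sign with replicate 4 turned, miR-241 (-0.57), miR-230 (-0.25) and miR-51 (-0.25), and 0 with replicate 1 turned. Some others kept their sign but changed in size. miR-83 fell to 0.14 with replicate 4 turned. With replicate 1 turned, miR-63 stood at 0.01 and miR-65 at -0.06, while miR-51 rose to 0.71. With replicate 4 turned, the alpha-synuclein calls against N2 came to 3, as the shared spread changed while the alpha-synuclein log2 changes did not.

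Between strains, where a dye bias that is constant over arrays cancels, let-7 was 3.40-fold lower in the alpha-synuclein strain than in the pdr-1 mutant (log2 difference -1.76 ± 0.49 SE, adjusted p = 0.0193). It was the 1 call among 48 microRNAs, from strain means of -1.80 and -0.04. The call was lost, with differences of -1.17 to -1.76, without any of alpha-synuclein replicates 1 and 2 and pdr-1 replicates 1, 2 and 4, and the adjusted p-values were then 0.0596 to 0.286. With scale normalization between arrays the 1 call was miR-241, and let-7 no longer passed (-1.19, adjusted p = 0.0847). Against the cat-1 mutant, 0 of 48 microRNAs passed, and 4 had an unadjusted p under 0.05. The first 3 were let-7 (-1.63 ± 0.52, adjusted p = 0.103), miR-241 (-1.68 ± 0.59, adjusted p = 0.111) and miR-70 (-1.89 ± 0.74, adjusted p = 0.187), and the plain test gave 0 calls. The miR-241 difference was -0.61 without cat-1 replicate 3, and miR-70 was measured on 1 cat-1 array. Between the cat-1 and pdr-1 mutants, 0 of 46 microRNAs passed and 0 had an unadjusted p under 0.05. The first 3 were miR-58 (0.95), miR-51 (-0.98) and miR-66 (0.98), each with an adjusted p of 0.989.

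The let-7 family was also lower as a group in both contrasts of the alpha-synuclein strain. Its mean difference was -1.33 against the cat-1 mutant (adjusted p = 4.01e-06) and -1.25 against the pdr-1 mutant (adjusted p = 1.8e-05), with 4 of 4 members below 0 in each. With an estimated correlation these p-values were 0.000113 and 0.000372. The list test takes microRNAs, not arrays, as its units, so these p-values do not measure the spread between worm populations. Of 35 splits of the arrays, 2 gave a family difference as far from 0 against cat-1 and 1 did against pdr-1. Chance is therefore not excluded. Adjusted over the list alone, let-7, miR-84 and miR-241 passed in both contrasts, against 0 and 1 members over all tested microRNAs. The low alpha-synuclein mean of miR-84 came mostly from replicate 1 (-2.75). The miR-241 difference from pdr-1 was -1.78, and -0.06 with pdr-1 replicate 4 turned, which ended its pass over the list alone (adjusted p = 0.925). miR-84 no longer passed over the list alone against pdr-1 with replicate 1 turned (adjusted p = 0.0549). Without cat-1 replicate 3, let-7 was the 1 member that passed over the list alone against cat-1. Between the cat-1 and pdr-1 mutants the family mean differed by 0.08 (adjusted p = 0.816). No other list passed in any contrast. Without normalization within arrays, the median of all tested microRNAs against N2 lay at 1.84, above the family mean of 0.73. With dye-control centring the family mean against the cat-1 mutant turned to 0.71.

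The strains shared no called microRNA in either direction, as 2 of them had no calls. Across microRNAs, which are not independent replicates, the strain means correlated at 0.317 for alpha-synuclein and pdr-1 (n = 48 microRNAs), 0.144 for alpha-synuclein and cat-1 (48) and 0.122 for cat-1 and pdr-1 (46). Without each array in turn these ranged from 0.152 to 0.360, 0.0556 to 0.233 and -0.0527 to 0.439. With pdr-1 replicate 4 turned, the correlation of cat-1 and pdr-1 was -0.207. Simulated strains with no effect that shared N2 preparations by replicate number, with N2 assumed to carry an equal part of the error, gave 0.283, 0.350 and 0.207. That sharing is an assumption that the labels do not state and that the arrays do not show, so these values are no measured baseline. The observed covariances were 0.0895, 0.0332 and 0.0203, against simulated values of 0.027, 0.0268 and 0.00985. With the arrays of each strain taken from different replicate numbers, the median correlations were 0.216, 0.0568 and 0.420.

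The authors' deposited table of log2 ratios did not hold the same values as the scanner files throughout. In 10 of 12 columns every value equalled the log2 ratio of the spot's own signals, centred by the ratio of summed signals, within a tolerance of 0.0001. The cat-1 replicate 4 column held values for 33 probes that matched no scanner file analysed here. In the alpha-synuclein replicate 2 column, 1 of 126 values matched the spot's own signals, while 126 of 126 equalled the ratio of the spot's own first signal and the second signal of some spot, each spot being used once. Fitted on this table, the alpha-synuclein strain had 4 calls against N2, let-7, miR-48, miR-54 and miR-70, and the contrast with the pdr-1 mutant had 0.

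**Figure D3:**
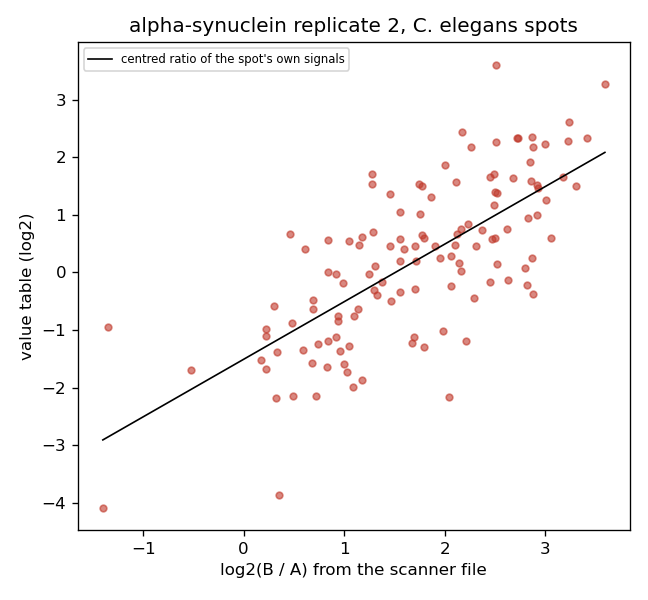
Each of 126 points is a C. elegans spot of alpha-synuclein replicate 2, with the log2 ratio of its scanner signals on the horizontal axis and the value of the deposited table on the vertical axis. The line marks where values of the spot's own signals would fall, and 1 of the 126 lies on it within 0.0001.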

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

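The tests of explanations in this part were chosen after the results were seen; the counts of other sign patterns and other splits of the arrays were planned, apart from those with a pdr-1 array turned.

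The let-7 family stood lower in the alpha-synuclein strain than in both mutants by a test of the difference itself, with mean log2 differences of -1.33 against cat-1 and -1.25 against pdr-1, and let-7 alone differed from pdr-1 by -1.76. For the family mean, the contrasts with cat-1 (-1.33) and pdr-1 (-1.25, and -0.90 with pdr-1 replicate 4 turned) argue against a constant dye bias. For miR-48 they leave it open, with limma differences of -0.83 from cat-1 (adjusted p = 0.795) and -0.35 from pdr-1 (adjusted p = 0.956). miR-241, at 1.05 in cat-1 and 1.15 in pdr-1 on 2 arrays each, adds to the family difference. The list test without each alpha-synuclein array in turn (adjusted p at most 0.0158) argues against a single array. The call of let-7 itself against N2, however, was lost without replicate 2 (-1.21, adjusted p = 0.0827). Relative to the median of all tested microRNAs, the family mean was at most -0.68 over the normalizations run, with and without loess. This argues against an intensity trend. Subtracting that median undoes most of a change in centring, so these values cannot decide whether centring lowered the family. The family mean itself was 0.73 against N2 without normalization and 0.71 against cat-1 with dye-control centring. Its distance from the median of 28 others measured on as many arrays (-1.09) argues against frequent measurement. Worms at an earlier larval stage may also lower the family, and lin-4, at -0.51 with an SD of 1.61 over 3 arrays and between -1.62 and 1.61 over the settings run, leaves that open. An effect of the transgene stays open as a hypothesis, and the list test takes microRNAs, not arrays, as its units.

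For the family against pdr-1, 1 of 35 splits of the 8 arrays gave a mean as far from 0 (real size 1.25, highest other 1.15), and 1 of 35 with pdr-1 replicate 1 turned (1.21, highest other 1.12). With pdr-1 replicate 4 turned, 3 of 35 did (0.90, highest other 1.00), and the direction of replicate 4 is not settled. A share of 1 of 35 is the smallest that these splits allow and was not adjusted for the other split tests. Chance is therefore not excluded with either direction. Against cat-1, 2 of 35 splits of the 7 arrays did (real size 1.33, highest other 1.56), so chance is not excluded. For the family against N2, 1 of 8 sign patterns gave a mean as far from 0 (real size 1.09, highest other 0.93), which are too few patterns for a share under 0.05. The same limit holds for the 5 alpha-synuclein calls against N2 (1 of 8 patterns, highest other 3). For the contrasts, the 1 call against pdr-1 was matched by 2 of 35 splits (highest other 1), so chance is not excluded. A count of 0 is matched by any split, so the 4 of 4 and 8 of 8 sign patterns for cat-1 and pdr-1 against N2 (highest other 0), and the 35 of 35 splits for alpha-synuclein against cat-1 (highest other 3) and cat-1 against pdr-1 (highest other 0), say nothing about chance.

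The deposited column of alpha-synuclein replicate 2 differed from its scanner file. Its values pair each spot's own first signal with the second signal of another spot, apart from 1 value. The second signal of some spot matched 126 of 126 values, with 126 different spots used, and 1 of them was the spot's own. In a simulated check, 2 of 150 random values were matched by chance. How this pairing arose was not tested. That the scanner file instead holds the wrong order is argued against by the spots of a probe, whose median SD was 0.302 in the scanner file and 0.784 in the table, against 0.130 to 0.586 on the other arrays. No biological explanation was tested.

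The SD of log2 ratios between probes was 0.511 on pdr-1 replicate 2, far from the 0.612 to 0.625 of the other pdr-1 arrays. It was the 1 such value among 24 groups of 4 tested, and chance gives about 1 in 20. miR-58 lay above 0 on every cat-1 array and below 0 on every pdr-1 array that measured it (-0.25, -0.05 and -0.0027, the last on replicate 4, whose direction is not settled), with means of 0.85 and -0.10 and a difference of 0.95. This was singled out by direction alone, and the limma contrast gave an adjusted p of 0.989.

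Signals also appeared in data outside the comparisons. Of 939 probes named by a number, 3 held a signal on every array, and their targets are not given. On the cat-1 arrays 15, 18 and 18 blank spots held a signal, against 3 on pdr-1 replicate 2 and 0 on the other arrays. Of 57 mutated or shuffled probes, 3 held a signal on any array. The deposited column of cat-1 replicate 4 held values for 33 probes, which correlated at 0.577, 0.451 and 0.538 with cat-1 replicates 1, 2 and 3 and at -0.740 with alpha-synuclein replicate 4 over the 8 probes shared with it.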

How the results depend on the processing

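The settings with the cat-1 replicate 4 column, dye controls, summed signals, number-named probes, the table with each strain alone, at least 3 arrays per strain, without the sparsest arrays and with turned signs were chosen after seeing the data; the others were planned. Of the results that answer a comparison, 385 values stayed, 64 moved and 3 reversed. A count of calls stayed if it changed by at most 1.5 times, whichever microRNAs were called. Comparisons that remained at 0 calls are among these. A correlation stayed if it moved less than its SD over resampled microRNAs, and a list if it passed and its mean kept its sign. Of named microRNAs 2037 stayed, 37 passed only under an alternative and 74 no longer passed. A further 90 uncalled values changed sign, and 6 called values reversed. Where not stated, the cause was not tested.

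The 5 alpha-synuclein calls against N2 (2 higher, 3 lower) became 8 with median centring (3 higher, 5 lower), 18 without normalization (18 higher, 0 lower), 8 with the cat-1 replicate 4 column, a setting that used median centring too and called the same 8 as median centring alone, 3 with pdr-1 replicate 4 turned, and 1 with scale normalization, signals on all arrays in both channels, each strain alone, array weights, or the table with each strain alone. They became 0 with a plain t-test and with dye-control centring. Calls against N2 rose from 0 to 1 (scale), 4 (each strain alone) and 7 (5 higher, 2 lower; table, each strain alone) in cat-1, and to 1 (scale) in pdr-1; scale also gave 1 between cat-1 and pdr-1.

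The 1 call against pdr-1 became 0 without normalization, with both channels on all arrays, each strain alone, the t-test, the table, the table with each strain alone, dye controls, or without the 2 sparsest arrays. With scale normalization the count stayed at 1 but the call was miR-241 in place of let-7 (let-7 -1.19, adjusted p = 0.0847). It became 2 with array weights, with a threshold of 0.1 and with an unadjusted p under 0.01, and 3 with the cat-1 replicate 4 column and median centring, against 1 with median centring alone. The 0 calls against cat-1 became 1 with array weights, the cat-1 replicate 4 column with median centring (0 with median centring alone) or at least 3 arrays per strain, and 2 with an unadjusted p under 0.01.

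Without normalization the median of all tested microRNAs moved from 0.14, 0.08 and 0.00 to 1.84, 0.78 and 2.08 in alpha-synuclein, cat-1 and pdr-1, and with dye-control centring to 1.62, -0.28 and 1.73. Against N2, let-7 then reversed to 0.19, miR-70 to 0.36, miR-48 to 0.63 and the let-7 family to 0.73 without normalization, and miR-70 to 0.15, miR-48 to 0.40 and the family to 0.51 with dye controls, where the family against cat-1 reversed to 0.71. Relative to the median of all tested, the family against N2 stayed between -1.46 and -0.68. The 3 passing lists, all the let-7 family, became 5 without normalization and 4 with dye controls. There the family still passed as lower than the rest, and the stress and lifespan list as higher. With both channels on all arrays the 3 lists were all the miR-63 family, as miR-48 alone of the let-7 family was left there. The miR-63 family means were -0.41 (cat-1 against N2), 0.18 (alpha-synuclein against cat-1) and -0.30 (cat-1 against pdr-1). The list test gave adjusted p-values of 0.0418, 0.0104 and 0.00529. That setting left 7 microRNAs, so miR-63, miR-64 and miR-65 were set against few others, and no other list had enough members.

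The correlation of alpha-synuclein and pdr-1 (0.317) became 0.479 without normalization, 0.450 with no filter, 0.907 with both channels on all arrays and 0.508 with dye controls. The value of 0.907 rests on 7 microRNAs. That of cat-1 and pdr-1 (0.122) became 0.308 without normalization and -0.207 with pdr-1 replicate 4 turned, and that of alpha-synuclein and cat-1 (0.144) became 0.310 with the cat-1 replicate 4 column and median centring, which alone gave 0.187.

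Without each array in turn, calls ranged from 1 to 5 (alpha-synuclein against N2), 0 to 1 (against cat-1) and 0 to 1 (against pdr-1), and 0 to 0 elsewhere; lists stayed at 3. The family ranged from -1.48 to -0.82 against N2, -1.72 to -1.06 against cat-1 and -1.63 to -0.98 against pdr-1. Correlations ranged from 0.0556 to 0.233, 0.152 to 0.360 and -0.0527 to 0.439 for alpha-synuclein with cat-1, alpha-synuclein with pdr-1 and cat-1 with pdr-1.

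Replicate numbers are shared between strains but did not pair the arrays: deviations of same-numbered arrays correlated at -0.779 to 0.116, and 0 arrays correlated best with their own number. With a random replicate block the calls were 3 against N2 and 2 against pdr-1, with a fixed block 3 against N2. These were let-7, miR-48 and lin-4 (-1.62, adjusted p = 0.0481), while miR-34 turned to -0.39 and the let-7 family against pdr-1 stood at -0.94. Background alternatives, slide or scan blocks and fry were not run.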

Other observations

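The tests in this part were chosen after the results were seen. Of the 7 microRNAs with a ratio on every array, miR-48, miR-64, miR-65 and miR-80 lay below 0 on at least 9 of 11 arrays, and 0 lay above 0 on as many. With pdr-1 replicate 1 or 4 turned, miR-64 and miR-65 lay below 0 on 8 of 11 and miR-48 and miR-80 on 9 of 11. These names were chosen after their values were seen. The 50 tested microRNAs, which include these, are not independent replicates, so a permutation over them does not measure the spread between arrays. Across them, the mean log2 ratio fell with the number of arrays that gave one (Spearman correlation -0.584, permutation p = 4e-05). It went from a mean of 0.29 for 6 microRNAs on at most 4 arrays to -0.22 for 15 on at least 9. That dim microRNAs have a ratio only where the strain channel is bright might give such a relation. If each channel were detected on its own, this would leave spots with an N2 signal and no strain signal. There was 1 such spot against 61 of the reverse kind, 47 of them on alpha-synuclein replicate 3. The reverse kind was more frequent on 7 arrays and less frequent on 0 (exact two-sided sign test, p = 0.0156). On most arrays, however, nearly all spots with a signal held it in both channels, as on cat-1 replicate 2 (126 in each channel and 126 in both). The channels may thus not be detected separately, and these counts cannot decide the question. A dye bias of these probes cannot be told apart from a change shared by all strains, since every array has the same orientation. The highest strain mean of the 4 was -0.11 as taken, and -0.06 (miR-65 in pdr-1) with pdr-1 replicate 1 turned.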
